A study of Mus musculus with 16 samples.

How the data were processed

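Poly-A selected RNA of mouse prostate was measured by RNA sequencing in 16 samples (TruSeq libraries on an Illumina HiSeq2000). Per the submitters' processing notes the authors used CASAVA 1.8.2, TopHat, Cufflinks, DESeq and DESeq2 with genome build mm9; which tool made the deposited table is not stated. The deposited values are normalized expression on a log2 scale. The base was inferred, since values taken out of log2 sum to similar, plausible read totals per library (log2 totals of 24.07 to 24.55). Low values look like those of a regularized log scale, which was not tested and would understate fold changes of genes with low expression. Read depth per library is not given and no whole reads could be recovered, so counting errors treat values taken out of log2 as reads.

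Groups came from the labels: wild type on vehicle (n = 3), wild type on finasteride (n = 5), mutant on vehicle (n = 3) and mutant on finasteride (n = 5). The sample titles carry running numbers that pair nothing, and all libraries share 1 age, 12 months. The labels do not state that each library is a separate animal, so p-values measure the spread between these samples only.

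The 16503 genes with a mean of at least 10 after taking the values out of log2 were tested. A linear model of the 4 group means was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3, with variance moderated along a trend in expression. Contrasts were the genotype effect on vehicle, the finasteride effect in wild type, the finasteride effect in the mutant, the genotype effect on finasteride, and the interaction. P-values were adjusted by Benjamini and Hochberg over the tested genes, with a threshold of 0.05. Errors beside fold changes are moderated standard errors. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 43 lists, and again with an estimated correlation and with fry, which does not compare a list with other genes. Agreement between effects was described by correlation and covariance across genes, beside 100 simulations of unchanged groups.

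Comparisons, their tests, the rule for named genes and the gene lists were fixed before the data were examined. The fit on 11 libraries, the seminal vesicle covariate and most tests of explanations were chosen afterwards. The lists were androgen response genes, genes that rise after androgen withdrawal, steroid receptors and enzymes, prostatic secretory proteins, proximal luminal, luminal and basal epithelium, neuroendocrine cells, smooth muscle, skeletal muscle, fibroblasts and matrix, endothelium, adipocytes, nerve and glia, macrophages and dendritic cells, T and NK cells, B and plasma cells, neutrophils and mast cells, antigen presentation, interferon response, cytokines and chemokines, seminal vesicle, epididymis and vas deferens, urothelium, red blood cells, cell cycle, antioxidant enzymes, oxidative phosphorylation, tricarboxylic acid cycle and zinc handling, fatty acid synthesis, cholesterol synthesis, polyamine metabolism, unfolded protein response, immediate early genes, heat shock, STAT5 and prolactin signalling, prostate developmental transcription factors, prostate tumour suppressors and oncogenes, apoptosis, epithelial mesenchymal transition, Wnt, cytosolic ribosome, and mucosal secretion. Symbols were matched through synonyms of a GRCm38.p6 annotation, used for nothing else, so no coordinates are given.

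Named genes were Srd5a1, Srd5a2, Pbsn and Fkbp5 in every comparison; some other genes that the rule names are not reported here. The rule added, among genes past the threshold with a mean of at least 50 and no overlap between the groups (not required for the interaction), the 10 highest and 10 lowest fold changes, leaving out predicted models. It also added the 4 members with the lowest p of each list that passed, and the most abundant member of lists of other cell types. Since this gave over 100 names in each comparison, the text names a subset, mostly genes whose call was kept over 11 libraries and without any 1 library, chosen after the values were seen.

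The model was tested on simulated data with the 16503 tested genes. With 16 independent libraries it recovered 62% of genes changed by 1 log2 unit and 90% of those changed by 2 in the genotype effect on vehicle, 67% and 93% in the finasteride effect in wild type, 70% and 88% in the mutant, 74% and 95% in the genotype effect on finasteride, and 49% and 82% in the interaction. Without any change it called a mean of 0 genes. With 5 of the 16 libraries simulated as mixtures of others, it called a mean of 301.2 to 514.8 unchanged genes, and 17.2% to 19.6% of their p-values were under 0.05 before adjustment.

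Each library was compared with mixtures of pairs of its own group over genes with a log2 value of at least 8. Those with both weights over 0.2 and a residual under 0.1 were treated as mixture-like, and the tests were repeated on the other 11 libraries. Further alternatives were other pseudocounts, no filter or a mean of at least 100, median-ratio and quantile normalization, a fit with only the groups compared, library weights, no variance trend, an additive fit, leaving out each library, and a seminal vesicle score as a covariate.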

Results

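RNA from the prostates of mice aged 12 months on a mixed strain background was sequenced after poly-A selection. Mice were wild type (+/+) or homozygous mutant (-/-) for 1 gene, and received vehicle or finasteride, a drug that blocks the 5-alpha-reductases that turn testosterone into dihydrotestosterone. The 16 libraries comprised 3 of wild type on vehicle, 5 of wild type on finasteride, 3 of mutant on vehicle and 5 of mutant on finasteride. Read depth per library is unknown, since the deposited table holds normalized log2 expression. The values, taken out of log2, summed to a log2 total of 24.07 to 24.16 in the 5 mutant finasteride libraries and 24.31 to 24.55 in the other 11. The 10 most abundant genes took 9.58% to 31.2% of that sum. Of the genes in the table, 16503 were tested. Fold changes are log2 values ± SE, and the scale of the deposited values appears shrunken, which would understate changes of genes with low expression.

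On the first principal component of all tested genes (50.7% of the variance) the vehicle groups lay between the finasteride groups, with wild-type finasteride at one end and mutant finasteride at the other. Libraries 3 of wild-type vehicle, 4 of wild-type finasteride, 3 of mutant vehicle, and 3 and 4 of mutant finasteride lay within 0.058 to 0.0914 log2 units of a mixture of a pair of other libraries of their group. Each comparison was therefore also fitted on the other 11 libraries, a choice made after the data were seen, because p-values over 16 libraries are too small if these 5 are not separate samples. Genes with near-identical copies, such as Klk1b22, H2-Q10, Ren1 and the Svs, Scgb2b, antibody and ribosomal genes, are uncertain where reads could have been split between copies.

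**Figure D1:**
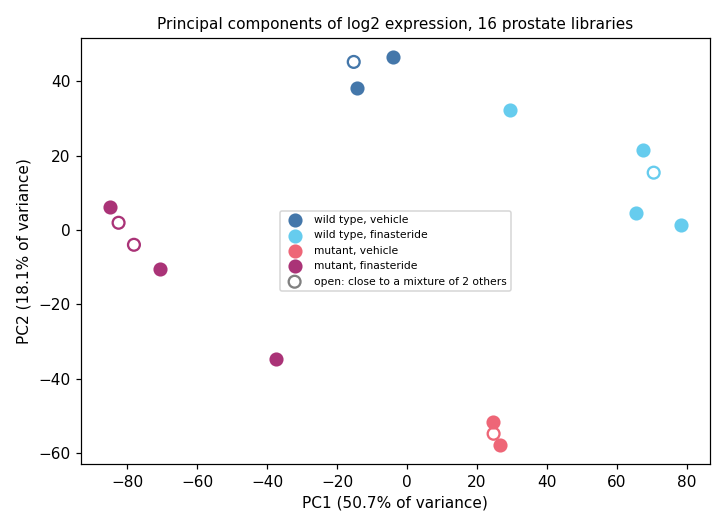
First and second principal components of the log2 expression of the tested genes, with 1 point per library, coloured by group, and percent of variance on each axis. Wild-type and mutant finasteride libraries lie at opposite ends of the first component (50.7%), and open points are the 5 libraries close to a mixture of a pair of others.

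**Figure D2:**
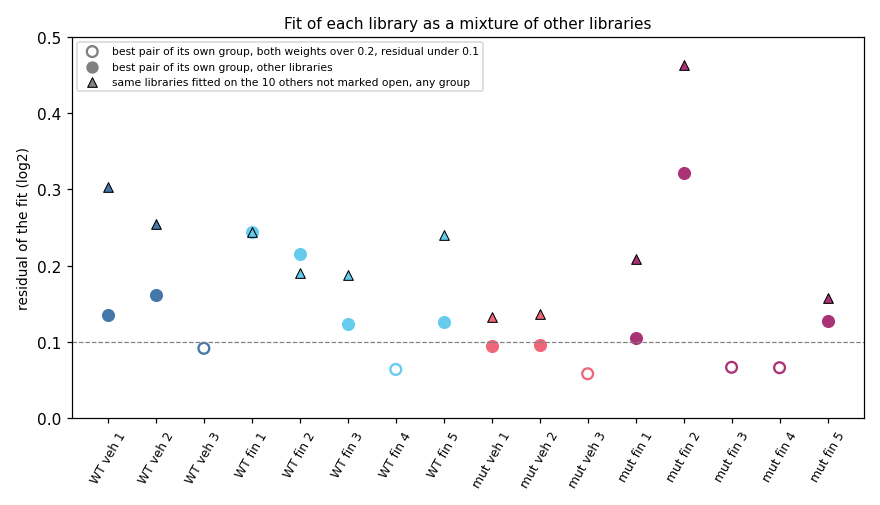
Residual (log2) of each library fitted as a mixture of a pair of libraries of its own group (circles), and, for the 11 libraries not marked open, of the 10 others of these 11 from any group (triangles), with a dashed line at 0.1. The 5 open circles lie at 0.058 to 0.0914, the filled circles at 0.0946 to 0.321, and the triangles at 0.133 to 0.463.

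The first question was what the mutation alone does to the prostate, from mutant against wild type on vehicle (n = 3 and 3). Probasin (Pbsn), an androgen-driven secretory protein, fell by 2.54 ± 0.25 on the log2 scale (limma adjusted p = 3.62e-06). Wfdc12 (10.35 ± 0.55), Klk1b22 (7.67 ± 1.43) and Wfdc6b (4.23 ± 0.47) were higher, and beta-microseminoprotein (Msmb, -6.48 ± 0.75) and the histocompatibility gene H2-Q10 (-7.74 ± 1.03) lower. The prostatic secretory list did not pass (camera adjusted p = 0.0968). The purine nucleoside transporter Slc28a2 (6.06 ± 0.47), Srpx (4.40 ± 0.60) and Nipal4 (4.37 ± 0.41) and Sectm1b (3.83 ± 0.16) were also higher, whereas Crabp1 (-8.72 ± 1.62), which binds retinoic acid, and Atp2c2 (-6.78 ± 1.26), a calcium and manganese pump, were lower.

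Genes tied to androgen action were lower more often than higher. The androgen response genes Odc1 (-0.96 ± 0.093), the first enzyme of polyamine synthesis, and Tmprss2 (-0.85 ± 0.089), a membrane serine protease, were lower. Of 32 androgen response genes, 4 were higher, 16 were lower and 12 did not pass (4 and 16 adjusted over the list alone). Androgen response genes had a camera adjusted p = 0.0278, and adjusted p = 0.407 with an estimated correlation. Among steroid enzymes and receptors, Sult1e1 (-2.31 ± 0.19), which sulphates oestrogens, and Hsd17b7 (-1.23 ± 0.21) were lower. Of 16 receptor and steroid enzyme genes, 1 was higher, 7 were lower and 8 did not pass (2 and 8 adjusted over the list alone). Receptor and steroid enzyme genes had a camera adjusted p = 0.00935, and adjusted p = 0.327 with an estimated correlation. Fkbp5 (-1.26 ± 0.33), a co-chaperone induced by androgen, and Srd5a2 (-1.07 ± 0.22), the prostatic 5-alpha-reductase, were lower over 16 libraries but not past the threshold over 11 (limma adjusted p = 0.128 and 0.0914). Srd5a1 (-0.22 ± 0.14, limma adjusted p = 0.244, and 0.068 under quantile normalization) did not pass. Cholesterol synthesis genes were lower, with Insig1 (-0.95 ± 0.15), a sterol sensor partner. Of 20 cholesterol synthesis genes, 0 were higher, 14 were lower and 6 did not pass (0 and 14 adjusted over the list alone). Cholesterol synthesis genes had a camera adjusted p = 0.00221, and adjusted p = 0.5 with an estimated correlation.

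Basal epithelial genes were higher, with Trp63 (1.02 ± 0.12), the transcription factor of basal cells, Col17a1 (1.15 ± 0.16), a hemidesmosome collagen, and Jag2 (0.90 ± 0.13). Of 14 basal epithelial genes, 8 were higher, 1 was lower and 5 did not pass (8 and 1 adjusted over the list alone). Basal epithelial genes had a camera adjusted p = 0.00221, and adjusted p = 0.448 with an estimated correlation. Urothelial genes were higher, with the uroplakins Upk2 (3.17 ± 0.31) and Upk1b (1.94 ± 0.24) and Gata3 (1.35 ± 0.14). Of 5 urothelial genes, 3 were higher, 0 were lower and 2 did not pass (4 and 0 adjusted over the list alone). Urothelial genes had a camera adjusted p = 0.00533, and adjusted p = 0.407 with an estimated correlation. Fibroblast and matrix genes were lower, with the collagen Col6a3 (-2.66 ± 0.28), periostin (Postn, -1.18 ± 0.10), decorin (Dcn, -1.14 ± 0.18) and the growth factor Igf1 (-1.75 ± 0.21). Of 23 fibroblast and matrix genes, 0 were higher, 19 were lower and 4 did not pass (0 and 19 adjusted over the list alone). Fibroblast and matrix genes had a camera adjusted p = 5.87e-08, and adjusted p = 0.407 with an estimated correlation. Striated muscle markers were lower, with Myh1 (-4.90 ± 0.62), Myh2 (-3.29 ± 0.56) and Tnnt3 (-2.21 ± 0.39). Of 14 skeletal muscle genes, 1 was higher, 7 were lower and 6 did not pass (1 and 8 adjusted over the list alone). Skeletal muscle genes had a camera adjusted p = 0.00396, and adjusted p = 0.407 with an estimated correlation. Of 15 nerve and glial genes, 0 were higher, 12 were lower and 3 did not pass (0 and 15 adjusted over the list alone). Nerve and glial genes had a camera adjusted p = 3.43e-04, and adjusted p = 0.5 with an estimated correlation. None of these nerve genes passed over 11 libraries.

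Among the other lists that passed, of T and NK cell genes 9 were higher and 0 were lower of 19 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0028, adjusted p = 0.5 with an estimated correlation) and of cell cycle genes 5 were higher and 0 were lower of 31 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00704, adjusted p = 0.577 with an estimated correlation). Mcm5 (0.98 ± 0.17), a replication helicase subunit, was higher. No T and NK cell gene passed over 11 libraries. Of macrophage and dendritic cell genes 0 were higher and 11 were lower of 20 (0 and 11 adjusted over the list alone, camera adjusted p = 0.00358, adjusted p = 0.5 with an estimated correlation) and of epithelial mesenchymal transition genes 1 was higher and 9 were lower of 17 (1 and 9 adjusted over the list alone, camera adjusted p = 0.00704, adjusted p = 0.45 with an estimated correlation). Vimentin (Vim, -1.07 ± 0.14) and S100a4 (-1.89 ± 0.18) were lower. Of interferon response genes 3 were higher and 8 were lower of 23 (3 and 12 adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.653 with an estimated correlation) and of neuroendocrine genes 0 were higher and 7 were lower of 9 (0 and 7 adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.598 with an estimated correlation). The interferon-induced GTPase Mx1 (2.08 ± 0.22) was higher against that direction. Of adipocyte genes 0 were higher and 4 were lower of 13 (0 and 4 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.577 with an estimated correlation) and of smooth muscle genes 0 were higher and 4 were lower of 16 (0 and 1 adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.653 with an estimated correlation). Of oxidative phosphorylation genes 3 were higher and 1 was lower of 49 (0 and 0 adjusted over the list alone, camera adjusted p = 0.00833, adjusted p = 0.73 with an estimated correlation) and of cytosolic ribosome genes 3 were higher and 0 were lower of 40 (0 and 0 adjusted over the list alone, camera adjusted p = 0.00833, adjusted p = 0.689 with an estimated correlation). Over 11 libraries no neuroendocrine, adipocyte, smooth muscle, oxidative phosphorylation or ribosome gene passed by limma, and 1 macrophage gene and 1 cell cycle gene did.

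In the limma fit, 5299 genes passed (1879 by more than 1 log2 unit), 2408 higher and 2891 lower. Quantile normalization gave 2878 higher and 2454 lower. Groups did not overlap in 9204 genes (55.8%), against 10% by chance (more if not all libraries are separate). Over 11 libraries 1534 genes passed, 653 higher and 881 lower, and 1533 of these had passed in the same direction over 16. Of 43 lists, 18 passed, 0 of them with an estimated correlation (lowest adjusted p = 0.327).

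The second question was how the normal prostate responds to finasteride, from wild type on finasteride against wild type on vehicle (n = 5 and 3). Stress genes rose, with Ddit3 (2.75 ± 0.34), Atf3 (1.75 ± 0.17) and Atf4 (1.10 ± 0.11), transcription factors of the stress response, and Syvn1 (2.12 ± 0.27), a ubiquitin ligase of the endoplasmic reticulum. The androgen response genes Fkbp5 (-1.70 ± 0.30, limma adjusted p = 6.08e-04), Mme (-2.20 ± 0.14), the peptidase neprilysin, and Steap4 (-1.53 ± 0.17) fell, as did Srd5a2 (-1.33 ± 0.20) and trehalase (Treh, -5.00 ± 0.59). Pbsn (-0.22 ± 0.22, limma adjusted p = 0.449) did not pass, and under quantile normalization it passed in the other direction at 0.72.

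Srd5a1 (-0.28 ± 0.12, limma adjusted p = 0.0915, and 0.062 under quantile normalization) did not pass. Of 32 androgen response genes, 3 rose, 12 fell and 17 did not pass (3 and 13 adjusted over the list alone). Androgen response genes had a camera adjusted p = 0.0223, and adjusted p = 0.314 with an estimated correlation. Of 16 receptor and steroid enzyme genes, 2 rose, 7 fell and 7 did not pass (2 and 8 adjusted over the list alone). Receptor and steroid enzyme genes had a camera adjusted p = 0.0119, and adjusted p = 0.241 with an estimated correlation. The oestrogen receptor Esr2 (-1.15 ± 0.17) and Sult1e1 (-1.59 ± 0.17) fell. Secretory genes fell, with Msmb at -5.13 ± 0.67 (between -5.80, without wild-type finasteride library 2, and -4.55) and the defensin Defb50 (-3.43 ± 0.40). Of 10 prostatic secretory genes, 1 rose, 5 fell and 4 did not pass (1 and 5 adjusted over the list alone). Prostatic secretory genes had a camera adjusted p = 0.0102, and adjusted p = 0.314 with an estimated correlation. Proximal luminal markers fell, with clusterin (Clu, -1.58 ± 0.16), Ly6a (-1.02 ± 0.11) and Ppp1r1b (-1.19 ± 0.23). Of 13 proximal luminal genes, 2 rose, 10 fell and 1 did not pass (2 and 10 adjusted over the list alone). Proximal luminal genes had a camera adjusted p = 0.0115, and adjusted p = 0.314 with an estimated correlation.

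Stress lists rose. Of 29 unfolded protein response genes, 21 rose, 2 fell and 6 did not pass (21 and 2 adjusted over the list alone). Unfolded protein response genes had a camera adjusted p = 3.24e-08, and adjusted p = 0.314 with an estimated correlation. Heat shock genes rose, with the chaperone Hspa8 (1.54 ± 0.26) and the inducible Hspa1a at 3.44 ± 0.63 (4.08 without wild-type finasteride library 5), whereas Hspb8 (-0.58 ± 0.098) fell. Of 14 heat shock genes, 13 rose, 1 fell and 0 did not pass (13 and 1 adjusted over the list alone). Heat shock genes had a camera adjusted p = 3.22e-05, and adjusted p = 0.314 with an estimated correlation. Immediate early genes rose, with Jun (1.52 ± 0.12), Dusp1 (0.70 ± 0.11) and Nr4a2 (1.17 ± 0.18). Of 23 immediate early genes, 15 rose, 0 fell and 8 did not pass (15 and 2 adjusted over the list alone). Immediate early genes had a camera adjusted p = 5.35e-05, and adjusted p = 0.065 with an estimated correlation. Of 40 cytosolic ribosome genes, 25 rose, 0 fell and 15 did not pass (29 and 0 adjusted over the list alone). Cytosolic ribosome genes had a camera adjusted p = 1.19e-06, and adjusted p = 0.397 with an estimated correlation. None of these ribosome genes passed by limma over 11 libraries. Cell cycle genes fell, with the helicase subunits Mcm6 (-1.32 ± 0.17) and Mcm5 (-0.87 ± 0.15) and the transcription factor E2f1 (-1.94 ± 0.34). Of 31 cell cycle genes, 0 rose, 20 fell and 11 did not pass (0 and 23 adjusted over the list alone). Cell cycle genes had a camera adjusted p = 7.31e-06, and adjusted p = 0.314 with an estimated correlation. Their mean in wild-type finasteride library 2 (6.306) lay near that of vehicle (6.405), unlike the other 4 (5.234 to 5.489). Of 49 oxidative phosphorylation genes, 6 rose, 1 fell and 42 did not pass (1 and 0 adjusted over the list alone). Oxidative phosphorylation genes had a camera adjusted p = 0.00874, and adjusted p = 0.704 with an estimated correlation. None of these passed over 11 libraries.

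Lipid genes fell in several lists. Adipocyte genes fell, with leptin (Lep, -2.90 ± 0.33), resistin (Retn, -3.05 ± 0.39) and the lipase Lpl (-1.16 ± 0.18). Of 13 adipocyte genes, 0 rose, 12 fell and 1 did not pass (0 and 12 adjusted over the list alone). Adipocyte genes had a camera adjusted p = 7.31e-06, and adjusted p = 0.314 with an estimated correlation. Of fatty acid synthesis genes 1 rose and 8 fell of 20 (1 and 8 adjusted over the list alone, camera adjusted p = 0.0311, adjusted p = 0.246 with an estimated correlation) and of cholesterol synthesis genes 1 rose and 10 fell of 20 (1 and 12 adjusted over the list alone, camera adjusted p = 0.00354, adjusted p = 0.397 with an estimated correlation). The desaturase Scd1 (-0.95 ± 0.075), Dgat2 (-2.38 ± 0.22), which completes triglycerides, and Thrsp (-2.91 ± 0.30) fell.

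Of 23 fibroblast and matrix genes, 1 rose, 13 fell and 9 did not pass (1 and 17 adjusted over the list alone). Fibroblast and matrix genes had a camera adjusted p = 7.31e-06, and adjusted p = 0.314 with an estimated correlation. Of macrophage and dendritic cell genes 0 rose and 12 fell of 20 (0 and 14 adjusted over the list alone, camera adjusted p = 7.81e-05, adjusted p = 0.314 with an estimated correlation) and of B and plasma cell genes 0 rose and 5 fell of 12 (0 and 5 adjusted over the list alone, camera adjusted p = 0.00562, adjusted p = 0.246 with an estimated correlation). The mannose receptor Mrc1 (-1.16 ± 0.15), lysozyme (Lyz2, -1.12 ± 0.16) and the antibody joining chain Igj (-2.39 ± 0.27) fell. Of neutrophil and mast cell genes 0 rose and 4 fell of 5 (0 and 4 adjusted over the list alone, camera adjusted p = 0.00483, adjusted p = 0.314 with an estimated correlation) and of antigen presentation genes 0 rose and 6 fell of 15 (0 and 6 adjusted over the list alone, camera adjusted p = 0.0157, adjusted p = 0.61 with an estimated correlation). The mast cell proteases Cma1 (-1.78 ± 0.25) and Mcpt4 (-2.12 ± 0.34) fell. Of interferon response genes 0 rose and 13 fell of 23 (0 and 14 adjusted over the list alone, camera adjusted p = 6.48e-04, adjusted p = 0.406 with an estimated correlation) and of epithelial mesenchymal transition genes 2 rose and 8 fell of 17 (2 and 9 adjusted over the list alone, camera adjusted p = 0.0383, adjusted p = 0.405 with an estimated correlation). The transition list did not pass over 11 libraries (camera adjusted p = 0.068). Of nerve and glial genes 0 rose and 14 fell of 15 (0 and 15 adjusted over the list alone, camera adjusted p = 7.31e-06, adjusted p = 0.314 with an estimated correlation) and of neuroendocrine genes 0 rose and 9 fell of 9 (0 and 9 adjusted over the list alone, camera adjusted p = 9.17e-05, adjusted p = 0.314 with an estimated correlation). Sox10 (-1.72 ± 0.33), a glial transcription factor, and the granule protein Chga (-2.04 ± 0.35) fell. Of seminal vesicle genes 0 rose and 11 fell of 12 (0 and 11 adjusted over the list alone, camera adjusted p = 7.33e-04, adjusted p = 0.397 with an estimated correlation) and of skeletal muscle genes 1 rose and 6 fell of 14 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0411, adjusted p = 0.314 with an estimated correlation). Over 11 libraries 1 interferon response and 1 skeletal muscle gene passed, but no antigen presentation or seminal vesicle gene, and Svs2, a seminal vesicle secretion gene, lay at 19.94, 8.02 and 18.60 in the 3 wild-type vehicle libraries.

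In the limma fit, 6618 genes passed, 3034 higher and 3584 lower, and quantile normalization gave 3694 higher and 2678 lower. Groups did not overlap in 5875 genes (35.6%), against 3.57% by chance (more if not all libraries are separate). Over 11 libraries 1437 genes passed, 602 higher and 835 lower, all of them in the direction seen over 16. Of 43 lists, 24 passed, 0 of them with an estimated correlation (lowest adjusted p = 0.065), and 23 over 11 libraries.

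The third question was how the mutant prostate responds to finasteride, from mutant on finasteride against mutant on vehicle (n = 5 and 3). Antibody transcripts rose, with Igkc (7.22 ± 0.42), Ighm (6.25 ± 0.25) and Igj (6.19 ± 0.27), the light chain, the mu heavy chain and the joining chain. The mucosal defence genes lactoferrin (Ltf, 6.29 ± 0.53), Pigr (5.91 ± 0.60), which carries antibody across epithelium, and Lcn2 (3.30 ± 0.18) rose. Pbsn fell by 4.61 ± 0.22 (limma adjusted p = 1.65e-09) and Fkbp5 rose by 1.54 ± 0.30 (limma adjusted p = 6.45e-04). The proton pump Atp12a (-3.35 ± 0.12), Fut9 (-4.49 ± 0.33), Gad2 (-4.32 ± 0.74) and Pnliprp1 (-4.58 ± 0.70) fell, while Slc5a8 (6.17 ± 1.05), a monocarboxylate transporter, and Adam7 (6.96 ± 1.03) of the epididymis and vas deferens list rose. The mean of that list rose from 4.89 to 10.37, but stood at 6.44 in mutant finasteride library 2, where Adam7 lay at 8.32.

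Most immune lists rose. The B cell genes Ms4a1 (2.81 ± 0.20), Cd79b (3.31 ± 0.26) and Pou2af1 (3.44 ± 0.21) rose. Of 12 B and plasma cell genes, 11 rose, 0 fell and 1 did not pass (12 and 0 adjusted over the list alone). B and plasma cell genes had a camera adjusted p = 1.42e-08, and adjusted p = 0.00949 with an estimated correlation. This list was the 1 that passed with an estimated correlation. Macrophage genes rose, with the complement genes C1qa (1.41 ± 0.17) and C1qb (1.64 ± 0.21) and Ms4a7 (1.66 ± 0.13). Of 20 macrophage and dendritic cell genes, 19 rose, 0 fell and 1 did not pass (20 and 0 adjusted over the list alone). Macrophage and dendritic cell genes had a camera adjusted p = 7.25e-09, and adjusted p = 0.238 with an estimated correlation. T cell genes rose, with the receptor chain Cd3e (1.47 ± 0.23) and Cd8b1 (2.31 ± 0.26). Of 19 T and NK cell genes, 14 rose, 0 fell and 5 did not pass (15 and 0 adjusted over the list alone). T and NK cell genes had a camera adjusted p = 1.21e-04, and adjusted p = 0.347 with an estimated correlation. Of 15 antigen presentation genes, 14 rose, 0 fell and 1 did not pass (14 and 0 adjusted over the list alone). Antigen presentation genes had a camera adjusted p = 6.74e-06, and adjusted p = 0.347 with an estimated correlation. The class II gene H2-Aa (1.32 ± 0.17) and the peptide transporter Tap1 (0.69 ± 0.10) rose. Of cytokine and chemokine genes 11 rose and 0 fell of 15 (11 and 0 adjusted over the list alone, camera adjusted p = 8.68e-05, adjusted p = 0.0755 with an estimated correlation) and of interferon response genes 13 rose and 2 fell of 23 (13 and 2 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.702 with an estimated correlation). Cxcl17 (4.44 ± 0.48) and Ifit3 (1.30 ± 0.20) rose, whereas Mx1 (-2.25 ± 0.20) fell.

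Proximal luminal genes rose, with Ppp1r1b (3.18 ± 0.23), the keratin Krt7 (2.55 ± 0.24) and Ly6a (1.90 ± 0.11). Of 13 proximal luminal genes, 11 rose, 1 fell and 1 did not pass (11 and 1 adjusted over the list alone). Proximal luminal genes had a camera adjusted p = 7.17e-05, and adjusted p = 0.238 with an estimated correlation. Of 10 mucosal secretion genes, 7 rose, 2 fell and 1 did not pass (7 and 2 adjusted over the list alone). Mucosal secretion genes had a camera adjusted p = 0.00964, and adjusted p = 0.141 with an estimated correlation. The trefoil peptide Tff3 (4.87 ± 0.30) rose. Of 12 genes known to rise after androgen withdrawal, 7 rose, 1 fell and 4 did not pass (7 and 1 adjusted over the list alone). Genes known to rise after androgen withdrawal had a camera adjusted p = 0.0488, and adjusted p = 0.286 with an estimated correlation. Clu (1.46 ± 0.16) and the protease Mmp7 (1.96 ± 0.25) rose, and this list did not pass over 11 libraries (camera adjusted p = 0.0663). Antioxidant enzymes rose, with Gsta4 (2.56 ± 0.14), Gpx2 (2.57 ± 0.22) and Mgst1 (1.95 ± 0.14). Of 32 antioxidant genes, 14 rose, 5 fell and 13 did not pass (15 and 5 adjusted over the list alone). Antioxidant genes had a camera adjusted p = 0.00964, and adjusted p = 0.286 with an estimated correlation. Unfolded protein response genes fell, with the sensor Atf6 (-1.44 ± 0.061) and the chaperones Dnajc3 (-1.39 ± 0.14) and Hyou1 (-1.05 ± 0.17). Of 29 unfolded protein response genes, 1 rose, 21 fell and 7 did not pass (1 and 23 adjusted over the list alone). Unfolded protein response genes had a camera adjusted p = 1.76e-06, and adjusted p = 0.347 with an estimated correlation.

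Of 32 androgen response genes, 11 rose and 11 fell (11 and 11 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.632). Srd5a2 (0.84 ± 0.20, limma adjusted p = 0.00285) rose, though not over 11 libraries (limma adjusted p = 0.0917). Srd5a1 (0.34 ± 0.12, limma adjusted p = 0.0334) did not keep its call over 11 libraries, without any 1 of the mutant vehicle libraries, or without mutant finasteride library 5 (0.29), and stood at -0.12 under quantile normalization.

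Of endothelial genes 12 rose and 0 fell of 15 (14 and 0 adjusted over the list alone, camera adjusted p = 6.74e-06, adjusted p = 0.286 with an estimated correlation) and of fibroblast and matrix genes 15 rose and 0 fell of 23 (16 and 0 adjusted over the list alone, camera adjusted p = 5.21e-05, adjusted p = 0.397 with an estimated correlation). Pecam1 (0.94 ± 0.10) and the tight junction gene Cldn5 (1.49 ± 0.19) of endothelium, and Postn (1.12 ± 0.094), rose. Of smooth muscle genes 14 rose and 0 fell of 16 (16 and 0 adjusted over the list alone, camera adjusted p = 1.68e-04, adjusted p = 0.449 with an estimated correlation) and of epithelial mesenchymal transition genes 11 rose and 1 fell of 17 (11 and 1 adjusted over the list alone, camera adjusted p = 2.4e-04, adjusted p = 0.286 with an estimated correlation). Over 11 libraries 1 smooth muscle gene passed. Of nerve and glial genes 13 rose and 0 fell of 15 (13 and 0 adjusted over the list alone, camera adjusted p = 0.00126, adjusted p = 0.569 with an estimated correlation) and of skeletal muscle genes 7 rose and 0 fell of 14 (7 and 0 adjusted over the list alone, camera adjusted p = 0.00773, adjusted p = 0.286 with an estimated correlation). Of neuroendocrine genes 7 rose and 0 fell of 9 (7 and 0 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.608 with an estimated correlation), and over 11 libraries 1 of these passed and the list did not (camera adjusted p = 0.0692). Uchl1 (2.92 ± 0.55), abundant in neurons, S100b (1.58 ± 0.34) of glia and Myh1 (3.12 ± 0.55) of striated muscle rose.

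In the limma fit, 7995 genes passed, 4235 higher and 3760 lower, and quantile normalization gave 3294 higher and 4651 lower. Groups did not overlap in 8187 genes (49.6%), against 3.57% by chance (more if not all libraries are separate). Over 11 libraries 3337 genes passed, 1812 higher and 1525 lower, 3334 of them in the direction seen over 16. Of 43 lists, 18 passed and 16 over 11 libraries.

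**Figure D3:**
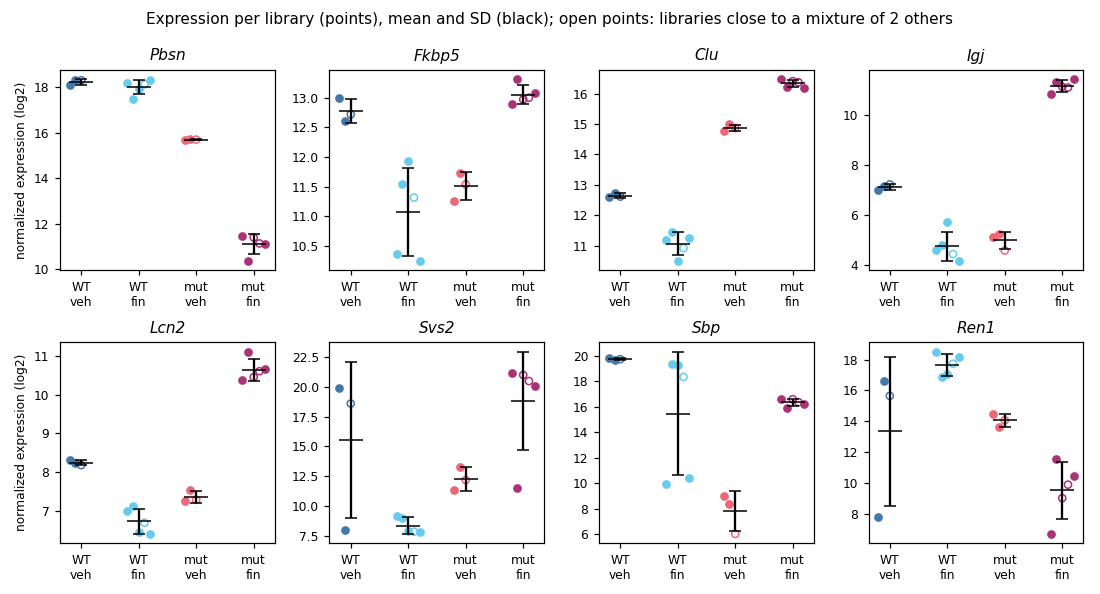
Log2 expression of 8 genes per library (points), with mean and SD in black, in the 4 groups of 3, 5, 3 and 5 libraries, and open points for the 5 libraries close to a mixture of a pair of others. Pbsn is lower in the mutant, Fkbp5, Clu, Igj and Lcn2 move in opposite directions under finasteride in the 2 genotypes, and Svs2, Sbp and Ren1 spread widely within single groups.

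The fourth question was how the genotypes differ under finasteride, from mutant against wild type on finasteride (n = 5 and 5). Pbsn fell by 6.92 ± 0.19 (limma adjusted p = 1.17e-12). Antibody genes Igkc (7.54 ± 0.36), Ighm (6.58 ± 0.22) and Igha (6.54 ± 0.59) were higher in the mutant, as were the protease inhibitor Wfdc12 (8.36 ± 0.43) and the seminal vesicle genes Svs3a (7.26 ± 1.49) and Svs2 (10.50 ± 2.02, and 12.33 without mutant finasteride library 2). Lower in the mutant were Fgl1 (-6.12 ± 0.22), a secreted fibrinogen-like protein, Pnliprp1 (-6.35 ± 0.61), Olfm4 (-5.59 ± 0.68), a secreted glycoprotein, Grin2d (-5.47 ± 0.36) and Mcoln3 (-5.64 ± 0.31), an endolysosomal channel. Fkbp5 (1.97 ± 0.26, limma adjusted p = 8.66e-06) and Srd5a2 (1.11 ± 0.17, limma adjusted p = 5.31e-05) were higher in the mutant.

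Srd5a1 (0.40 ± 0.11, limma adjusted p = 0.00501) was higher, but stood at -0.12 under quantile normalization. Clu (5.26 ± 0.14) and Ly6a (2.97 ± 0.095) were higher. Of 13 proximal luminal genes, 11 were higher, 1 was lower and 1 did not pass (11 and 1 adjusted over the list alone). Proximal luminal genes had a camera adjusted p = 4.07e-05, and adjusted p = 0.216 with an estimated correlation. Of 14 basal epithelial genes, 12 were higher, 1 was lower and 1 did not pass (12 and 1 adjusted over the list alone). Basal epithelial genes had a camera adjusted p = 0.00118, and adjusted p = 0.337 with an estimated correlation. Trp63 (1.21 ± 0.092) and the integrin Itgb4 (1.22 ± 0.064) were higher. Of 31 cell cycle genes, 25 were higher, 1 was lower and 5 did not pass (25 and 1 adjusted over the list alone). Cell cycle genes had a camera adjusted p = 4.07e-05, and adjusted p = 0.396 with an estimated correlation. Of 18 STAT5 and prolactin pathway genes, 11 were higher, 3 were lower and 4 did not pass (11 and 3 adjusted over the list alone). STAT5 and prolactin pathway genes had a camera adjusted p = 0.0186, and adjusted p = 0.216 with an estimated correlation. The survival gene Bcl2l1 (0.96 ± 0.095) and the kinase Jak2 (0.94 ± 0.082) were higher. Of antioxidant genes 18 were higher and 6 were lower of 32 (18 and 7 adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.337 with an estimated correlation) and of fatty acid synthesis genes 15 were higher and 3 were lower of 20 (15 and 3 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.176 with an estimated correlation). Qsox1 (5.50 ± 0.37), which forms disulphide bonds, Gpx2 (3.79 ± 0.19) and Scd1 (1.07 ± 0.065) were higher.

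Protein folding lists were lower in the mutant. Of 29 unfolded protein response genes, 0 were higher, 27 were lower and 2 did not pass (1 and 28 adjusted over the list alone). Unfolded protein response genes had a camera adjusted p = 3.37e-10, and adjusted p = 0.223 with an estimated correlation. Atf6 (-1.84 ± 0.053), Atf4 (-1.62 ± 0.096) and Hyou1 (-2.18 ± 0.15) and Chac1 (-4.29 ± 0.30), which breaks down glutathione, were lower. Of heat shock genes 1 was higher and 13 were lower of 14 (1 and 13 adjusted over the list alone, camera adjusted p = 7.57e-04, adjusted p = 0.428 with an estimated correlation) and of cytosolic ribosome genes 0 were higher and 22 were lower of 40 (0 and 21 adjusted over the list alone, camera adjusted p = 0.00173, adjusted p = 0.594 with an estimated correlation). Hspa8 (-2.03 ± 0.22) and Hsp90ab1 (-1.27 ± 0.14) were lower.

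Immune lists were higher. Of 19 T and NK cell genes, 19 were higher, 0 were lower and 0 did not pass (19 and 0 adjusted over the list alone). T and NK cell genes had a camera adjusted p = 4.65e-08, and adjusted p = 0.216 with an estimated correlation. Cd3e (2.67 ± 0.20) and Cd8a (3.11 ± 0.24) were higher. Of 12 B and plasma cell genes, 12 were higher, 0 were lower and 0 did not pass (12 and 0 adjusted over the list alone). B and plasma cell genes had a camera adjusted p = 1.88e-07, and adjusted p = 0.0204 with an estimated correlation. Igj (6.43 ± 0.23) and Cd79a (3.88 ± 0.22) were higher, and this list was the 1 that passed with an estimated correlation. Of macrophage and dendritic cell genes 19 were higher and 0 were lower of 20 (19 and 0 adjusted over the list alone, camera adjusted p = 8.13e-08, adjusted p = 0.223 with an estimated correlation) and of antigen presentation genes 15 were higher and 0 were lower of 15 (15 and 0 adjusted over the list alone, camera adjusted p = 4.21e-07, adjusted p = 0.337 with an estimated correlation). The class I light chain B2m (2.53 ± 0.18) was higher. Of cytokine and chemokine genes 11 were higher and 1 was lower of 15 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00162, adjusted p = 0.176 with an estimated correlation) and of interferon response genes 15 were higher and 2 were lower of 23 (15 and 2 adjusted over the list alone, camera adjusted p = 0.00985, adjusted p = 0.565 with an estimated correlation). Ccl5 (3.08 ± 0.26), which draws T cells, and Cxcl10 (1.97 ± 0.19) were higher. Of neutrophil and mast cell genes 5 were higher and 0 were lower of 5 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00981, adjusted p = 0.399 with an estimated correlation).

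Of endothelial genes 14 were higher and 1 was lower of 15 (14 and 1 adjusted over the list alone, camera adjusted p = 3.47e-04, adjusted p = 0.396 with an estimated correlation) and of fibroblast and matrix genes 13 were higher and 1 was lower of 23 (13 and 1 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.565 with an estimated correlation). Of epithelial mesenchymal transition genes 11 were higher and 1 was lower of 17 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.416 with an estimated correlation) and of adipocyte genes 11 were higher and 1 was lower of 13 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0038, adjusted p = 0.433 with an estimated correlation). Of nerve and glial genes 14 were higher and 0 were lower of 15 (14 and 0 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.503 with an estimated correlation) and of neuroendocrine genes 9 were higher and 0 were lower of 9 (9 and 0 adjusted over the list alone, camera adjusted p = 0.00249, adjusted p = 0.428 with an estimated correlation). Stmn2 (3.04 ± 0.58) of neurons and Scg2 (4.12 ± 0.76) of secretory granules were higher. Of seminal vesicle genes 9 were higher and 0 were lower of 12 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.565 with an estimated correlation).

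In the limma fit, 10497 genes passed, 5474 higher and 5023 lower, and quantile normalization, which moved the median of all genes from 0.008 to -0.10, gave 4305 higher and 6085 lower. Groups did not overlap in 6608 genes (40%), against 0.794% by chance (more if not all libraries are separate). Over 11 libraries 6774 genes passed, 3620 higher and 3154 lower, 6766 of them in the direction seen over 16. Of 43 lists, 23 passed, and 24 over 11 libraries.

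The main question was whether the response to finasteride depends on genotype, tested as the difference between the mutant and the wild-type finasteride effect over all 16 libraries (interaction). A positive value is a response that was higher in the mutant. Fkbp5 (3.24 ± 0.42), Srd5a2 (2.17 ± 0.28), Clu (3.03 ± 0.23) and the antibody genes Igkc (9.92 ± 0.59) and Igj (8.58 ± 0.38) had a higher response in the mutant. Pbsn (-4.38 ± 0.32) had a lower response in the mutant (limma adjusted p = 8.79e-08). So did Fut9 (-6.16 ± 0.47), Glb1l3 (-5.17 ± 0.49), Atp12a (-4.55 ± 0.18) and Mcoln3 (-5.13 ± 0.50). Srd5a1 (0.62 ± 0.18, limma adjusted p = 0.008) did not pass over 11 libraries (limma adjusted p = 0.0767) and stood at -0.18 under quantile normalization.

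Atf3 (-2.73 ± 0.24), Atf4 (-1.58 ± 0.16) and Atf6 (-1.86 ± 0.087) of the unfolded protein response and the chaperone Hspa8 (-2.14 ± 0.36) had a lower response in the mutant. Of 29 unfolded protein response genes, 1 was higher, 25 were lower and 3 did not pass (1 and 26 adjusted over the list alone). Unfolded protein response genes had a camera adjusted p = 1.14e-08, and adjusted p = 0.238 with an estimated correlation. Of heat shock genes 1 was higher and 12 were lower of 14 (1 and 12 adjusted over the list alone, camera adjusted p = 0.00591, adjusted p = 0.531 with an estimated correlation) and of cytosolic ribosome genes 0 were higher and 25 were lower of 40 (0 and 27 adjusted over the list alone, camera adjusted p = 1.8e-04, adjusted p = 0.555 with an estimated correlation). Of oxidative phosphorylation genes 2 were higher and 11 were lower of 49 (2 and 10 adjusted over the list alone, camera adjusted p = 0.0292, adjusted p = 0.757 with an estimated correlation), and this list did not pass over 11 libraries (camera adjusted p = 0.0909).

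Immune lists had a higher response in the mutant. Of 12 B and plasma cell genes, 11 were higher, 0 were lower and 1 did not pass (11 and 0 adjusted over the list alone). B and plasma cell genes had a camera adjusted p = 4.77e-07, and adjusted p = 0.024 with an estimated correlation. Pou2af1 (4.51 ± 0.30) and Ms4a1 (3.65 ± 0.28) were among them, and this list was the 1 that passed with an estimated correlation. Of 20 macrophage and dendritic cell genes, 20 were higher, 0 were lower and 0 did not pass (20 and 0 adjusted over the list alone). Macrophage and dendritic cell genes had a camera adjusted p = 2.19e-08, and adjusted p = 0.238 with an estimated correlation. Of T and NK cell genes 14 were higher and 0 were lower of 19 (16 and 0 adjusted over the list alone, camera adjusted p = 4.37e-04, adjusted p = 0.319 with an estimated correlation) and of antigen presentation genes 15 were higher and 0 were lower of 15 (15 and 0 adjusted over the list alone, camera adjusted p = 3.46e-05, adjusted p = 0.319 with an estimated correlation). Of cytokine and chemokine genes 11 were higher and 1 was lower of 15 (12 and 1 adjusted over the list alone, camera adjusted p = 6.45e-04, adjusted p = 0.188 with an estimated correlation) and of interferon response genes 18 were higher and 1 was lower of 23 (19 and 2 adjusted over the list alone, camera adjusted p = 8.55e-04, adjusted p = 0.488 with an estimated correlation). Lcn2 (4.81 ± 0.25) and Cxcl17 (6.30 ± 0.67) and Ifit3 (2.41 ± 0.28) were higher, and Mx1 (-2.24 ± 0.28) was lower. Of neutrophil and mast cell genes 5 were higher and 0 were lower of 5 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00552, adjusted p = 0.319 with an estimated correlation).

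Of proximal luminal genes 10 were higher and 3 were lower of 13 (10 and 3 adjusted over the list alone, camera adjusted p = 8.69e-04, adjusted p = 0.238 with an estimated correlation) and of mucosal secretion genes 7 were higher and 2 were lower of 10 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.238 with an estimated correlation). Ly6a (2.92 ± 0.15), Krt7 (3.71 ± 0.34) and Pigr (8.32 ± 0.84) were higher. Of antioxidant genes 19 were higher and 7 were lower of 32 (19 and 7 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.238 with an estimated correlation) and of genes known to rise after androgen withdrawal 8 were higher and 1 was lower of 12 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0214, adjusted p = 0.238 with an estimated correlation). Gsta4 (3.62 ± 0.20) and Gpx2 (4.57 ± 0.32) were higher. Of cholesterol synthesis genes 9 were higher and 1 was lower of 20 (9 and 1 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.555 with an estimated correlation) and of fatty acid synthesis genes 10 were higher and 2 were lower of 20 (10 and 2 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.238 with an estimated correlation). Scd1 (1.75 ± 0.11) was higher. Of cell cycle genes 11 were higher and 1 was lower of 31 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0473, adjusted p = 0.603 with an estimated correlation), but this list did not pass over 11 libraries (camera adjusted p = 0.0561) and turned to a median of -0.14 under quantile normalization, with 4 higher and 8 lower (camera adjusted p = 0.794).

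Of fibroblast and matrix genes 18 were higher and 0 were lower of 23 (18 and 0 adjusted over the list alone, camera adjusted p = 2.11e-06, adjusted p = 0.319 with an estimated correlation) and of endothelial genes 12 were higher and 0 were lower of 15 (12 and 0 adjusted over the list alone, camera adjusted p = 5.36e-04, adjusted p = 0.319 with an estimated correlation). Igf1 (3.11 ± 0.26), Postn (1.86 ± 0.13) and Pecam1 (1.19 ± 0.14) were higher. Of adipocyte genes 11 were higher and 0 were lower of 13 (12 and 0 adjusted over the list alone, camera adjusted p = 5.74e-04, adjusted p = 0.319 with an estimated correlation) and of epithelial mesenchymal transition genes 12 were higher and 0 were lower of 17 (12 and 0 adjusted over the list alone, camera adjusted p = 6.1e-04, adjusted p = 0.238 with an estimated correlation). Of nerve and glial genes 15 were higher and 0 were lower of 15 (15 and 0 adjusted over the list alone, camera adjusted p = 2.62e-05, adjusted p = 0.319 with an estimated correlation) and of neuroendocrine genes 9 were higher and 0 were lower of 9 (9 and 0 adjusted over the list alone, camera adjusted p = 5.74e-04, adjusted p = 0.319 with an estimated correlation). S100b (2.96 ± 0.47), Sox10 (2.88 ± 0.47) and Chga (3.85 ± 0.49) were higher. Of skeletal muscle genes 9 were higher and 1 was lower of 14 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00591, adjusted p = 0.238 with an estimated correlation) and of seminal vesicle genes 9 were higher and 0 were lower of 12 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.555 with an estimated correlation). Over 11 libraries 1 seminal vesicle gene passed. Of smooth muscle genes 5 were higher and 0 were lower of 16 (4 and 0 adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.59 with an estimated correlation), and this list did not pass over 11 libraries (camera adjusted p = 0.0616).

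Among lists that passed in another comparison, those that did not pass the interaction were androgen response genes (camera adjusted p = 0.389), prostatic secretory proteins (0.302), steroid receptors and enzymes (0.0531, and 0.0475 over 11 libraries), basal epithelial genes (0.607), urothelial genes (0.563), immediate early genes (0.287) and STAT5 and prolactin genes (0.0525). The 9 lists that passed in no comparison had these interaction results. Of luminal epithelial genes 4 were higher and 8 were lower of 18 (4 and 8 adjusted over the list alone, camera adjusted p = 0.678) and of epididymis and vas deferens genes 3 were higher and 0 were lower of 5 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0639). Of red blood cell genes 0 were higher and 0 were lower of 5 (0 and 0 adjusted over the list alone, camera adjusted p = 0.784) and of tricarboxylic acid cycle and zinc genes 4 were higher and 9 were lower of 24 (4 and 9 adjusted over the list alone, camera adjusted p = 0.154). Of polyamine genes 4 were higher and 5 were lower of 13 (4 and 5 adjusted over the list alone, camera adjusted p = 0.815) and of developmental transcription factors 9 were higher and 8 were lower of 27 (9 and 8 adjusted over the list alone, camera adjusted p = 0.956). Of prostate tumour suppressors and oncogenes 6 were higher and 7 were lower of 23 (6 and 7 adjusted over the list alone, camera adjusted p = 0.949) and of apoptosis genes 9 were higher and 7 were lower of 25 (10 and 7 adjusted over the list alone, camera adjusted p = 0.792). Of Wnt genes 8 were higher and 8 were lower of 19 (8 and 8 adjusted over the list alone, camera adjusted p = 0.984).

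**Figure D4:**
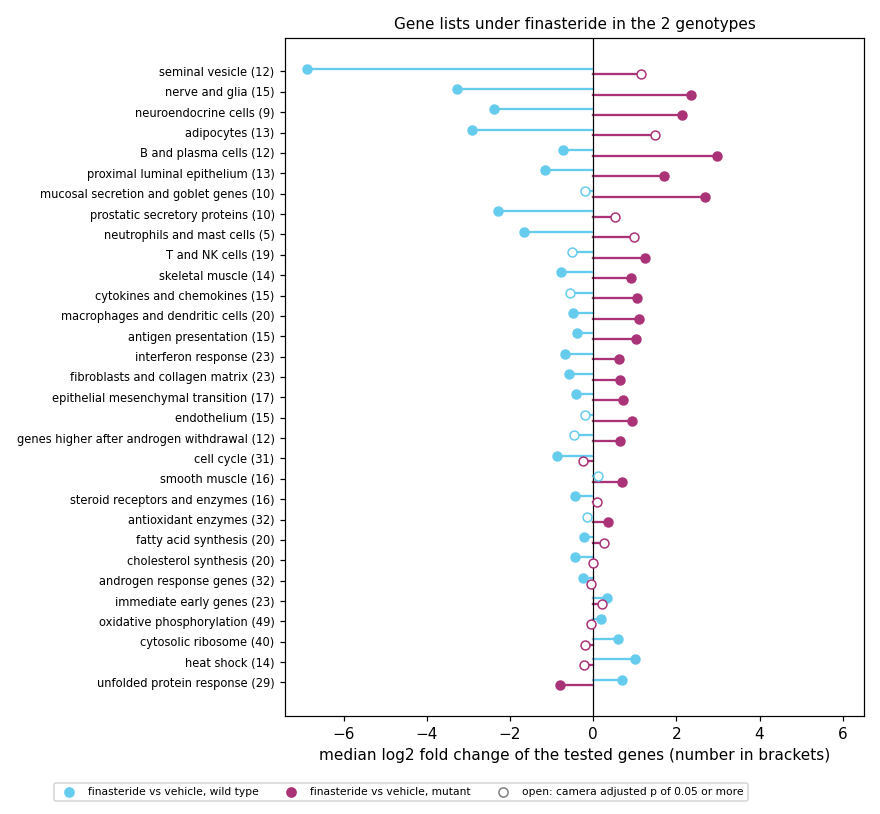
Median log2 fold change under finasteride of each gene list that passed in the finasteride effect of at least 1 genotype, in wild type and in the mutant, with the number of tested genes in brackets. Filled points passed camera at an adjusted p of 0.05, and lists of immune, fibroblast, nerve and proximal luminal genes lie on opposite sides of 0 in the 2 genotypes.

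In the limma fit, 9336 genes passed the interaction, 4855 higher and 4481 lower, and quantile normalization, which moved the median of all genes from -0.022 to -0.162, gave 3650 higher and 5547 lower. Over 11 libraries 4843 genes passed, 2816 higher and 2027 lower, 4839 of them in the direction seen over 16. Of 43 lists, 27 passed, and 25 over 11 libraries.

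Across the 16503 tested genes, which are not independent replicates, the finasteride effects of the 2 genotypes correlated negatively (Pearson r = -0.555, Spearman rho = -0.498, covariance -0.356) and shared their sign in 32.5% of genes. Those effects share no library, so the r of unchanged simulated groups (6.75e-04) was near 0 by design and is no test. Genes up in wild type and down in the mutant numbered 1308 (691.3 for independent lists), and the reverse 2002 (919.7). Up in both were 142 (778.6) and down in both 288 (816.6). The genotype effects on vehicle and on finasteride correlated at r = -0.164 (rho = -0.192, covariance -0.139). The finasteride effect in the mutant ran against the genotype effect on vehicle (r = -0.633, rho = -0.589, covariance -0.457). Those share the mutant vehicle libraries, for which unchanged simulated groups gave r = -0.542 and covariance -0.0946, a difference of -0.362, and 3 libraries are too few to split, so part of this relation can come from the shared group.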

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

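Tests chosen only after the results were seen were those of combined library material, of 1 axis in mutant finasteride, of a fixed seminal vesicle profile, of carry-over, of exchanged labels, and of a changed share of all other cell types. The finasteride effect differed between the genotypes, by the interaction test, in 9336 genes, 27 lists and 135 named genes.

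Dixon's test (critical value 0.71) sought a library far from the other 4 in the 2 groups of 5. Over 286 named genes and 43 lists (658 tests), 55 gene values and 10 list means stood apart. Chance does so in about 1 in 20 groups, or more if mixture-like ones are not separate. Srd5a1 stood at 7.16 in mutant finasteride library 5 and Srd5a2 at 6.91 in mutant finasteride library 2. In wild-type finasteride library 2, the list means of epididymis and vas deferens (10.69), cell cycle (6.31) and mucosal secretion (6.84) stood apart, and in library 1 of that group the mean of antioxidant enzymes (10.01). In mutant finasteride library 2, the means stood apart of genes higher after androgen withdrawal (11.07), seminal vesicle (10.87), epididymis and vas deferens (6.44), tricarboxylic acid cycle and zinc handling (10.73), STAT5 and prolactin signalling (9.64) and apoptosis (8.68). Among other named genes, wild-type finasteride libraries 1, 2, 3 and 5 stood apart in 9, 11, 1 and 2, and mutant finasteride libraries 1, 2, 3 and 5 in 1, 27, 1 and 1.

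The first pattern was that 5 of the 16 libraries lay between a pair of others of their group in 95.3% to 96.9% of the genes in which that pair lay more than 0.3 log2 units apart (731 to 4558 of 9030 genes), against at most 85.1% for the other 11 libraries with any pair. Separate animals along 1 axis of tissue content stay open. In wild-type finasteride the first component of the other 4 libraries held 69.8% of the variance. Yet library 4 needs only its pair, 3 and 5, on 1 axis. In mutant finasteride the first component of the other 3 held 89.1%, and libraries 3 and 4 met the limits with 2 and 3 pairs. Library 5 missed them with a residual of 0.127. In the vehicle groups a remaining pair cannot test it. Combined material of a pair of libraries may account for the 5, with residuals of at most 0.0914 log2 units, but the limit does not tell it apart, because mutant vehicle libraries 1 and 2, with all weight on library 3, lay at 0.0946 and 0.0952. Residuals of the 5 were 0.977 to 1.28 times the counting error at log2 values of 8 to 9 and 1.32 to 4.20 times above 13, and whether tissue, RNA, libraries or values were combined stays open.

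The second pattern was that seminal vesicle transcripts differed by group and library. A single seminal vesicle profile in varying amount is argued against, because members differed between the vehicle groups by a median of 2.18 log2 units relative to the list mean, against 0.672 inside groups. Carry-over from wild-type vehicle library 1 might account for the low level in library 2 of that group, where 10 members lay a mean of 11.7 log2 units lower with an SD of 0.342, a share of 0.0299%. A biological difference in the seminal vesicle or its secretion between genotypes stays open and untested.

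The third pattern was that finasteride effects ran opposite in the 2 genotypes. A changed share of all other cell types stays open. The highest and lowest changes of 7 other tissue lists lay 2.82 (SE 0.762) apart in wild type and 1.58 (SE 0.54) in the mutant. The SE ignores that these were picked. The amount of nerve, fat and seminal vesicle tissue stays open. With that covariate r was -0.308 (-0.428 to -0.292 without 1 library), against -0.562 without it, but unchanged groups were not simulated with it. Exchanged finasteride and vehicle labels among the mutants cannot be told apart from a response that depends on genotype. Both stay open, and neither was tested on other animals. In the mutant 11 androgen response genes rose and 11 fell, withdrawal genes rose 7 to 1, Fkbp5 and Srd5a2 rose, and Pbsn fell. In wild type the withdrawal list mean (10.966 to 10.329), Fkbp5 and Srd5a2 fell, and Pbsn did not pass.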

How the results depend on the processing

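Tests chosen after seeing the data were the fit without the 5 mixture-like libraries and the seminal vesicle score as a covariate. Causes not named were not tested. For the counts of genes and lists of each comparison and the correlations between effects, values not given here stayed within 1.5 times the count, or within 0.1 of the correlation. Without 1 library, the genes passing ranged from 3922 to 6282 in the genotype effect on vehicle, 4482 to 7606 in the finasteride effect in wild type, 6357 to 8818 in the mutant, 9766 to 11052 in the genotype effect on finasteride and 8342 to 10113 in the interaction, and the lists from 14 to 19, 22 to 26, 17 to 22, 23 to 24 and 23 to 29. The correlation of the finasteride effects ranged from -0.578 to -0.521, of the genotype effects from -0.201 to -0.137, and of the finasteride effect in the mutant with the genotype effect on vehicle from -0.647 to -0.616.

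Without the 5 mixture-like libraries 1534, 1437, 3337, 6774 and 4843 genes passed in the 5 comparisons, in the order above, with fewer libraries in each group. Library weights, which gave those 5 libraries weights of 2.03 to 7.87, raised the first 3 counts to 10569, 10856 and 12155 without reaching the convergence tolerance. The seminal vesicle covariate gave 1750 genes in the finasteride effect in wild type, 6981 in the genotype effect on finasteride and 6043 in the interaction. The additive fit, which assumes 1 finasteride effect and 1 genotype effect for all libraries, gave 1177 genes for either finasteride effect and 5630 for the genotype effect on finasteride. With an estimated correlation 0, 0, 1, 1 and 1 lists passed, whereas camera with the preset correlation passed 18, 24, 18, 23 and 27, and fry passed 28 in the finasteride effect in the mutant and 37 in the genotype effect on finasteride. With a mean of at least 100, where fewer genes were tested, 11 lists passed in the genotype effect on vehicle. The direction with more calls then differed in all 5 comparisons, as it did under quantile normalization (0 and at most 4 calls reversed), with 2046, 2827, 2311, 3002 and 2575 higher and 1808, 2130, 3419, 4445 and 4092 lower. Without a filter, the finasteride effects correlated at -0.454.

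Of the reported named genes, values changed sign in 91 cases. In the additive fit this follows from averaging opposite effects. For the genotype effect on vehicle it gave Srd5a1 0.16, Srd5a2 0.29, Fkbp5 0.76, Spink5 0.27, Scgb2b7 0.97, Chga 0.82, Scg3 0.70, Chgb 0.93, Scg2 1.37, Pcp4 0.20, Sncg 1.56, Igf1 0.19, Retn 0.87, Fabp4 1.01, Plin4 0.21, Uchl1 0.92, S100b 0.12, Stmn2 0.63, Sox10 0.23, Mrc1 0.58, Ms4a7 0.53, C1qa 0.49, C1qc 0.47, Lyz2 0.90, Uqcrc2 -0.033, Stard4 0.16, Vim 0.26, Rps16 -0.13. For the finasteride effect in wild type it gave Srd5a1 0.034, Ren1 -0.10, Pnliprp1 -0.87, Mt3 -0.13, Mug1 1.479, Sult1e1 0.15, Ly6a 0.44, Ppp1r1b 0.996, Actn3 0.004, Myh1 0.13, Mb 0.52, Postn 0.19, Mrc1 0.001, Emr1 0.004, Igj 1.90, Pou2af1 1.19, Ms4a1 0.98, Sdc1 0.15, Kit 0.79, H2-DMb1 0.065, Nlrc5 0.20, H2-DMa 0.15, Ifit3 0.099, Hspb8 0.45, Vim 0.24. For the finasteride effect in the mutant it gave Srd5a2 -0.24, Fkbp5 -0.080, Clu -0.059, Chga -0.12, Scg3 -0.23, Eno2 -0.10, Nrsn1 -0.76, Sfrp1 -0.005, Igf1 -0.30, Dcn -0.10, Eng -0.052, Uchl1 -0.17, Lyz2 -0.097, Il33 -0.12, Hyou1 0.11, S100a4 -0.010. For the genotype effect on finasteride it gave Postn -0.015, Dcn -0.038. Quantile normalization gave Srd5a1 0.068, Lpl -0.048 in the genotype effect on vehicle, and Srd5a1 0.062, Pbsn 0.72, Kit 0.20 in the finasteride effect in wild type, and Srd5a1 -0.12 in the finasteride effect in the mutant, and Srd5a1 -0.12 in the genotype effect on finasteride, and Srd5a1 -0.18, Lck -0.34 in the interaction. Library weights gave Lpl -0.039 in the genotype effect on vehicle, and Ncam1 0.042 in the finasteride effect in the mutant. The seminal vesicle covariate gave Kit 0.42, Svs5 1.66 in the finasteride effect in wild type, and Svs5 -0.98 in the interaction. Leaving out 1 library gave Lpl -0.16 in the genotype effect on vehicle without wild-type vehicle library 2, Sdc1 0.026 in the finasteride effect in wild type without wild-type vehicle library 2, Sdc1 0.050 in the finasteride effect in wild type without wild-type finasteride library 2, Sdc1 0.008 in the finasteride effect in wild type without wild-type finasteride library 3, Lpl -0.087 in the genotype effect on vehicle without mutant vehicle library 2, Ncam1 0.024 in the finasteride effect in the mutant without mutant finasteride library 2 (-0.11 to 0.024 over libraries).

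Over all reported named genes and alternatives, 14716 results kept direction and side of the threshold, 620 kept direction but no longer passed, and 40 newly passed. Of the called named genes, 47 of 96, 45 of 115, 17 of 99, 5 of 120 and 14 of 135 no longer passed without the 5 mixture-like libraries. No paired analysis was possible because the sample titles pair nothing. Tests on read counts were not run, since no whole reads could be recovered. Depth is unknown, so what it limits could not be given, and changes of genes with low expression would be understated if the deposited scale is shrunken.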

Other observations

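Tests in this part were planned before the results were seen, apart from the splits of 11 libraries, and the genes were chosen after their values were seen. Genes of the male tract outside the prostate stood out in single libraries. Crisp1 and Akr1b7, secretory genes of the epididymis and the vas deferens, lay at log2 values of 13.42 and 15.18 in wild-type finasteride library 2, against at most 4.12 and 4.91 in the other 4 of that group. In mutant finasteride libraries 1, 3, 4 and 5 Crisp1 lay at 14.30, 14.07, 13.69 and 13.27, and in library 2 at 4.54. Akr1b7 lay at 15.23, 15.06, 14.65 and 14.09 in the former and 5.39 in the latter. In the finasteride effect in the mutant, 4 of 5 tested genes of the epididymis and vas deferens list rose (4 adjusted over the list alone), with a median of 6.96, but the list did not pass (camera adjusted p = 0.0956).

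Some secretory genes differed widely between libraries of 1 group, whereas Pbsn had an SD of 0.319 in wild-type finasteride. Sbp, a spermine-binding secretory protein, lay at 9.95 and 10.39 in wild-type finasteride libraries 1 and 5, and at 19.36, 19.31 and 18.34 in libraries 2, 3 and 4. The protease inhibitor Spink3 followed, at 7.97 and 8.52 against 17.25, 16.68 and 15.68. Svs2, a seminal vesicle secretion gene, lay at 19.94, 8.02 and 18.60 in wild-type vehicle libraries 1, 2 and 3, and Ren1, which encodes renin, at 7.84, 16.58 and 15.65. Svs2 minus Svs4 was 0.744 to 0.831 in wild-type vehicle, -3.61 in wild-type finasteride library 1 and 0.527 to 1.36 in the other 4, -4.72 to -3.96 in mutant vehicle, and -4.73 in mutant finasteride library 2 against 3.995 to 6.602 in the other 4. Transglutaminase 4 (Tgm4), a coagulating protein of the prostate, lay at 15.62, 17.00, 16.05, 16.16 and 16.54 in the 5 mutant finasteride libraries and between 18.49 and 19.74 in the other 11.

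Other splits of the libraries of each comparison, the real one included, showed how often a result as large arose. For the genotype effect on vehicle, the 10 splits are too few for a share under 0.05. There 1 split gave as many genes (real 5299, highest other 0, whereas 1534 passed by limma over 11 libraries) and 1 as many lists (real 18, highest other 17). The next values count the 5 mixture-like libraries as separate samples, with the splits that gave as many, the real count and the highest other in brackets. For finasteride in wild type, chance is unlikely for genes (1 of 56, 6618, 3386) and narrowly for lists (2 of 56, 24, 25). For the finasteride effect in the mutant, chance is unlikely for genes (1 of 56, 7995, 3426) but not for lists (6 of 56, 18, 19). For the genotype effect on finasteride, chance is unlikely for genes (1 of 100, 10497, 7283) and narrowly for lists (4 of 100, 23, 24). For the interaction, chance is unlikely for genes (1 of 100, 9336, 7528) and for lists (1 of 100, 27, 25). Without those 5 the splits are too few for a share under 0.05 in the finasteride effect in wild type, for genes (1 of 15, 1437, 398) and lists (1 of 15, 23, 19), and in the mutant, for genes (1 of 10, 3337, 136) and lists (3 of 10, 16, 16). For the genotype effect on finasteride over 11 libraries, chance is unlikely for genes (1 of 35, 6774, 3362) and lists (1 of 35, 24, 22). In the interaction over 11 libraries chance is unlikely for genes (1 of 100, 4843, 1073) and lists (1 of 100, 25, 23).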
